A study of Sus scrofa with 12 samples.

How the data were processed

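The data are 12 poly-A RNA-seq libraries of pig heart, 6 of left ventricular pressure overload and 6 of referent controls, grouped by the group label of each sample. Per the labels' protocols, libraries were made with a directional kit. The submitters' processing notes name FastQC, Trim Galore 0.4.5, STAR 2.7.2b, SAMtools 1.5, featureCounts of Subread 1.5.3 and the genome build Sscrofa11.1. The annotation, the strand setting and the treatment of multi-mapping reads are not given in the sources used here.

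The data are held in a single table made by the authors. Its 12 library columns and 2 group means hold CPM (read counts scaled by library size), per the file headers, and whether the authors rescaled the libraries first is not given. The authors' comparison gives a log2 fold change and a mean log2 CPM per gene, per the file headers. It also gives a likelihood-ratio statistic, a score that the authors computed from a generalized linear model, and an unadjusted and an adjusted p-value, as deposited. The deposited group means equal the means of the columns. The table holds 516 genes, and the largest unadjusted p in the authors' deposited table is 0.04997, so the genes were chosen on the outcome. The ratio of adjusted to unadjusted p in the authors' deposited table implies that 15235 genes were tested, of which 3.39% are listed. Benjamini-Hochberg values recomputed from the listed p-values equalled those of the authors' deposited table for the 103 genes with an adjusted p under 1 (largest gap 7.42e-14), so the list is complete to that rank. Beyond it the list cannot be checked, and if the authors filtered it further, the hypergeometric p-values and the counts of list members not listed describe that filtered list. Values of the other genes were not analysed here.

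Depth was found by searching, per library, for the size between 18 and 36 M reads at which CPM values become whole reads. On average 95.8% of values up to 5000 reads were whole within 0.02 reads and 99.6% were whole when multiplied by 3, as a fractional count of reads that map to several places would give. Because not all values are whole reads, no count model was fitted. Simulated libraries gave back 12 of 12 sizes within 0.1%. No 2 libraries had identical values, and correlations between libraries ranged from 0.786 to 0.971 over the listed genes.

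CPM values were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(CPM + 1), for genes with a CPM of at least 1 in at least 6 libraries. This left 512 genes; COMP, TRIB3, RAB3B and SLC9A2 were under the filter. A log2 difference on this scale understates the change of low genes. The plan, written for a table of all genes, was to adjust over the genes tested. Taken as the genes of this table, that would be circular, since each was listed for an unadjusted p under 0.05 in the same libraries. After the table was seen to be partial, the genes tested were taken as the authors' 15235, with unlisted genes counted as having larger p-values, and adjustment over the table alone became an alternative. On simulated data for the same comparison with 512 genes, limma called 67% of 100 genes changed 2-fold, 93% of 100 changed 4-fold and 0% of 312 unchanged genes, of which 5.77% had an unadjusted p under 0.05. These shares are not the power in the real table, where 34 lower and 15 higher genes had an absolute log2 fold change of 1 or more. The simulation changed more genes that strongly, which eases the adjustment, and drew each gene independently. A lack of calls in the real data therefore does not argue against 2-fold changes. Single genes were also compared with an exact two-sided permutation test of 6 against 6 libraries. Each gene had been listed for a difference in these same libraries, so its permutation p is not independent support. Python 3.11.15 with SciPy 1.17.1 was used for the other tests.

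Before the data were examined, 35 gene lists were written from the series title, the tissue and the cell types that heart tissue can hold, together with the alternatives and the rule for named genes. The lists do not hold every gene of their theme, so counts of members describe the lists as written. The set tests planned for a table of all genes were not run on a table chosen by p. Lists with at least 5 listed members were tested for direction against the other listed genes with Fisher's exact test. A hypergeometric test of the number of listed members among the 15235 tested genes was added after the data were seen. Its list size is the number of annotated members, which can exceed the number tested and makes the test conservative, while its assumption of independent genes makes p too small where members vary together. The rule for named genes takes the 10 largest changes per direction among genes that pass or, if none passes, the 10 smallest limma p-values, up to 4 listed members per list by the authors' p, and 18 preset genes. It named 57 genes. ETV1, the remaining members of lists, genes named only as lying outside a list, and genes named under other observations were chosen after their values were seen.

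Symbols were matched for 514 of 516 genes, 501 in the Ensembl and 490 in the RefSeq name table. Coordinates are those of NCBI RefSeq on Sscrofa11.1. Of the 57 named genes, 16 overlap another annotated gene, among them RGS6, CYFIP2, TRPM7, PLEKHA7, CLK2, CLK3, AGO4, P4HA1, SERPINH1, HIF1A, CXCL10 and ND6, and ETV1 overlaps one as well; their counts are uncertain where counting could not separate the genes. Alternatives covered the pseudocount (0.1, 0.5 and 5), the filter, the scaling of libraries, the variance model, library weights, a term for the description-number series, and leaving out each library.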

Results

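Messenger RNA of pig heart was profiled after 5 weeks of left ventricular pressure overload, which was produced by an inflatable cuff around the ascending aorta. The series text describes 9 pigs with pressure overload and 6 age- and weight-matched referent control pigs, and the libraries analysed here are 6 of pressure overload and 6 of controls. Polyadenylated RNA was sequenced from strand-specific libraries. The title of the series frames the study as a model of heart failure with preserved ejection fraction and points to matrix pathways and to regulation after transcription, so these gene groups are described first among the lists below. Each library carries its own identifier, but the labels do not state that each came from a separate pig. The p-values therefore measure the spread between these libraries. Effective library size, recovered from the step between neighbouring CPM values, averaged 26.3 M ± 3.51 M reads (SD, n = 12) and ranged from 19.5 to 31.9 M reads. It was 25.3 M ± 4.21 M in controls and 27.3 M ± 2.66 M in pressure overload (SD, n = 6 each), a difference within the spread between libraries (exact permutation p = 0.346, two-sided).

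In the authors' deposited table, 6 genes passed an adjusted p of 0.05, of which 5 fell and 1 rose in pressure overload. TNNI1, which encodes the slow skeletal troponin I isoform that is also made in the fetal heart, fell from 26.3 ± 20.4 CPM in controls to 3.49 ± 1.29 CPM in pressure overload (SD, n = 6 each). RGS6, a regulator of G protein signalling, fell from 20.1 ± 17.0 to 2.64 ± 1.08 CPM. ETV1, an ETS-family transcription factor, fell from 54.3 ± 16.2 to 28.6 ± 4.79 CPM, PLEKHA6, a pleckstrin homology domain protein, from 53.6 ± 16.5 to 28.9 ± 5.91 CPM, and GRAMD1C, a membrane protein of the sterol transfer family, from 21.4 ± 9.06 to 8.53 ± 2.91 CPM. TM4SF18, a small membrane-spanning protein, rose from 7.22 ± 2.94 to 15.7 ± 3.25 CPM.

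The log2 fold changes of the 5 genes that fell were -2.87 for TNNI1, -2.87 for RGS6, -1.32 for GRAMD1C, -0.92 for ETV1 and -0.89 for PLEKHA6 in the authors' deposited table, and that of TM4SF18 was 1.10. The adjusted p in the authors' deposited table was 0.0298 for TNNI1, 0.0406 for GRAMD1C and 0.0367 for each of the other 4 genes. Within replicates 1 to 3 and within replicates 4 to 6, the log2 differences were -2.83 and -1.71 for TNNI1, -1.43 and -2.85 for RGS6, -0.81 and -0.90 for ETV1, -0.45 and -1.23 for PLEKHA6, -0.94 and -1.49 for GRAMD1C, and 0.81 and 1.46 for TM4SF18; a shared sign is favoured by listing on these same libraries. The control and pressure overload libraries did not overlap for TNNI1, PLEKHA6, GRAMD1C and TM4SF18. They overlapped for RGS6, where the lowest control was at 3.17 CPM and the highest pressure overload library at 4.28 CPM, and for ETV1, where these were 31.7 and 31.8 CPM. TNNI1 lies on chromosome 10 from 23788279 to 23800554 (Sscrofa11.1, NCBI RefSeq annotation), and TM4SF18 on chromosome 13 from 89527835 to 89549515. A mean of 626 reads in controls and 96.3 in pressure overload stood behind TNNI1, and 184 and 425 behind TM4SF18.

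**Figure D1:**
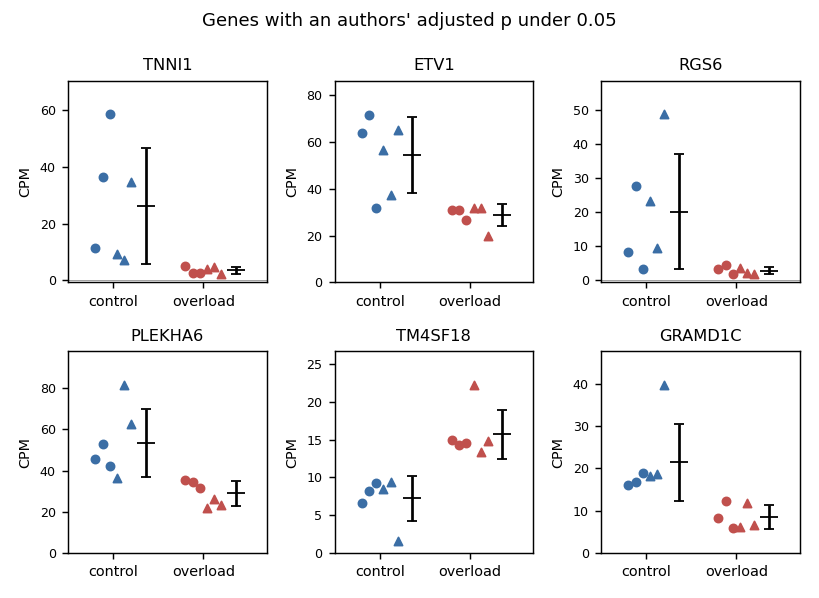
CPM of the 6 genes with an adjusted p under 0.05 in the authors' deposited table, in 6 control (blue) and 6 pressure overload (red) libraries; circles are replicates 1 to 3, triangles replicates 4 to 6, and bars the mean ± SD. TNNI1 was at 26.3 CPM in controls and 3.49 CPM in pressure overload, with a control SD of 20.4 CPM.

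The limma test of the same CPM values called none of these genes and no other. After Benjamini-Hochberg adjustment over the 15235 genes that the authors tested, limma called 0 genes higher and 0 lower, and its smallest adjusted p was 0.624, shared by TNNI1, GRAMD1C and CYFIP2, with log2 differences of -2.27 ± 0.43, -1.22 ± 0.24 and -1.36 ± 0.27 (SE). At an unadjusted p under 0.05 limma gave 117 genes higher and 339 lower of the 512 fitted, but the listed genes had all been chosen at that level by the authors' own test of these libraries. The total of 456 was 195 after median-of-ratios and 241 after upper-quartile rescaling of the libraries. Here and below, the rescaling factors were computed on the listed genes, most of them lower. This builds in an upward shift that shrinks decreases and enlarges increases. Rescaled values therefore do not show whether a decrease comes from scaling. The direction in limma was that of the authors for 512 of 512 genes.

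The authors' deposited table lists 516 genes, 375 lower and 141 higher in pressure overload, with an unadjusted p under 0.05 for each. Among 15235 tested genes, 761.75 would be under 0.05 if none differed and the p-values were uniform. The count of 516 is therefore no excess over chance, though whether the list was filtered further is not known. The median log2 fold change in the authors' deposited table was -0.51 for the lower and 0.44 for the higher genes, and 34 lower and 15 higher genes had an absolute log2 fold change of 1 or more. The control and pressure overload libraries did not overlap for 50 of the 516 genes, or 9.69%. The chance rate of 0.216% applies to genes not chosen on the comparison. Listing required a difference in these libraries, so the share cannot be set against that rate. By summed CPM, the listed genes took 4.06% ± 0.321 of the library size in controls and 3.10% ± 0.40 in pressure overload (SD, n = 6 each; exact permutation p = 0.00433, two-sided), on genes chosen because they differed. These are shares of all counts only if the authors did not rescale the libraries first, which is not given. Without ND6, whose value is uncertain, the shares were 2.54% ± 0.177 and 2.18% ± 0.171 (exact permutation p = 0.00866).

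**Figure D2:**
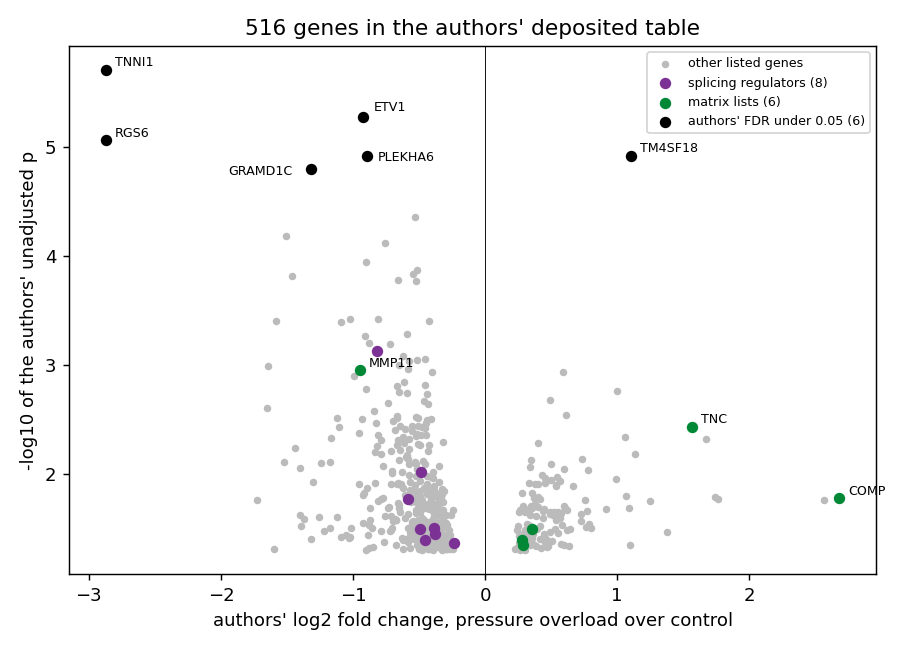
Log2 fold change (pressure overload over control) against -log10 of the unadjusted p of the 516 genes in the authors' deposited table, one point per gene; black marks the 6 genes with an adjusted p under 0.05, purple the 8 listed splicing regulators and green the 6 listed members of the matrix lists. Of the 516 genes, 375 lie left of 0 and 141 right of it.

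Among the genes with the smallest limma p that were lower, CYFIP2, a component of the WAVE actin regulatory complex, was at 53.6 ± 21.8 CPM in controls and 19.4 ± 5.97 CPM in pressure overload (exact permutation p = 0.00433, n = 6 each). TRPM7, a cation channel with a kinase domain, was at 98.2 ± 10.97 and 68.2 ± 10.8 CPM, and its adjusted p in the authors' deposited table was 0.0946. PLEKHA7, an adherens junction protein, was at 65.8 ± 14.8 and 37.5 ± 9.19 CPM, SEMA4B, a semaphorin, at 19.6 ± 3.08 and 12.3 ± 1.04 CPM, and ZNF672, a zinc finger protein, at 33.8 ± 8.39 and 18.05 ± 3.999 CPM. Among the genes that were higher, GFPT2, an enzyme of the hexosamine pathway, was at 4.57 ± 1.45 CPM in controls and 9.29 ± 1.94 CPM in pressure overload (exact permutation p = 0.00433, n = 6 each). CKB, the brain-type creatine kinase, was at 13.4 ± 2.14 and 29.5 ± 17.4 CPM, and LRP11, an LDL receptor-related protein, at 26.7 ± 4.92 and 40.4 ± 5.39 CPM. GNB4, SERP1, SDCBP2, ST3GAL1 and KCTD12 had log2 differences of 0.54, 0.46, 0.93, 0.49 and 0.91. None of these passed limma's adjusted threshold or that of the authors. The single-gene permutation p-values here and below come from the libraries on which the genes were listed, so they add no independent support.

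Of 178 genes in 5 matrix lists, 6 were listed, 1 lower and 5 higher, where at most 6.03 were expected from the share of tested genes that is listed (exact hypergeometric p = 0.563). MMP11, a matrix metalloproteinase, was at 151 ± 11.9 CPM in controls and 78.1 ± 37.7 CPM in pressure overload, a log2 difference of -1.10 ± 0.27 (SE; exact permutation p = 0.00433, n = 6 each). SERPINH1, the collagen chaperone HSP47, was at 229.7 ± 27.6 and 280 ± 47.4 CPM, P4HA1, a prolyl hydroxylase of collagen, at 53.7 ± 11.97 and 68.9 ± 10.3 CPM, and FERMT2, an integrin activator of focal adhesions, at 173 ± 19.8 and 211 ± 22.6 CPM. TNC, a matricellular glycoprotein, was at 6.11 ± 1.71 and 18.3 ± 22.9 CPM, and its ratio of means of 3.002 was 1.502 without pressure overload replicate 4. COMP, a cartilage matrix glycoprotein, was at 0.117 ± 0.141 and 1.43 ± 2.95 CPM, and its ratio of 12.2 was 1.98 without the same library. The exact permutation p was 0.115 for TNC and 0.195 for COMP. By list, the listed genes were 2 of 49 matricellular proteins, proteoglycans and glycoproteins, 2 of 48 matrix proteases and inhibitors, 2 of 23 collagen processing genes, with SERPINH1 counted among both the inhibitors and the processing genes, 1 of 37 integrin and focal adhesion genes, and 0 of 22 collagens. None of the 6 passed the adjusted test of limma or of the authors. The counts describe the lists as written. The integrin ITGA2B, the integrin ligand NPNT and the metalloproteinases ADAMTS3, ADAMTS6 and ADAMTS15 were among the listed genes outside the 5 matrix lists. These are examples and not a full account.

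Of 48 genes of TGF-beta and BMP signalling, 3 were listed. The ligand BMP4 was at 12.95 ± 2.18 CPM in controls and 8.77 ± 1.98 CPM in pressure overload, the receptor ACVR2A at 32.7 ± 3.63 and 25.2 ± 3.96 CPM, and SKI, a repressor of TGF-beta signalling, at 39.8 ± 7.40 and 52.8 ± 12.3 CPM (SD, n = 6 each). After median-of-ratios rescaling the log2 difference was -0.05 for ACVR2A in place of -0.37, -0.22 for BMP4 in place of -0.52 and 0.71 for SKI in place of 0.39. This upward shift is built in by factors from mostly lower genes. The list was not enriched (exact hypergeometric p = 0.221).

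Splicing regulators were the list with the largest excess of listed genes. Of 41 members, 8 were listed, all lower as deposited, with RBFOX2 at a log2 difference of 0.10 after median-of-ratios rescaling, where at most 1.39 were expected (exact hypergeometric p = 5.84e-05, adjusted p = 0.00205 over 35 lists). NOVA1, a neuronal-type splicing factor, was at 15.5 ± 2.13 CPM in controls and 8.75 ± 2.19 CPM in pressure overload (SD, n = 6 each; exact permutation p = 0.00216, the smallest that 6 against 6 libraries can give). The kinases of SR splicing proteins CLK1, CLK2 and CLK3 were at 90.8 ± 22.9 and 60.5 ± 26.8 CPM, 36.1 ± 6.11 and 25.9 ± 5.42 CPM, and 25.9 ± 3.87 and 19.8 ± 5.79 CPM. The other members were CLK4, SRSF11, SF3B1 and RBFOX2, with log2 differences of -0.50, -0.49, -0.40 and -0.22. In limma, 8 of 8 passed when adjusted over the list alone and 0 when adjusted over all genes tested, and the first count is not independent evidence because listing required a difference. The direction test against the other listed genes could not pass even with 8 of 8 lower (Fisher's exact test, two-sided p = 0.115), because most listed genes were lower. The hypergeometric test treats genes as independent, which these were not. The median log2 difference was -0.48, with -0.13 in replicates 1 to 3 and -0.81 in replicates 4 to 6. After median-of-ratios rescaling of the libraries, which builds in an upward shift, the median was -0.16.

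**Figure D3:**
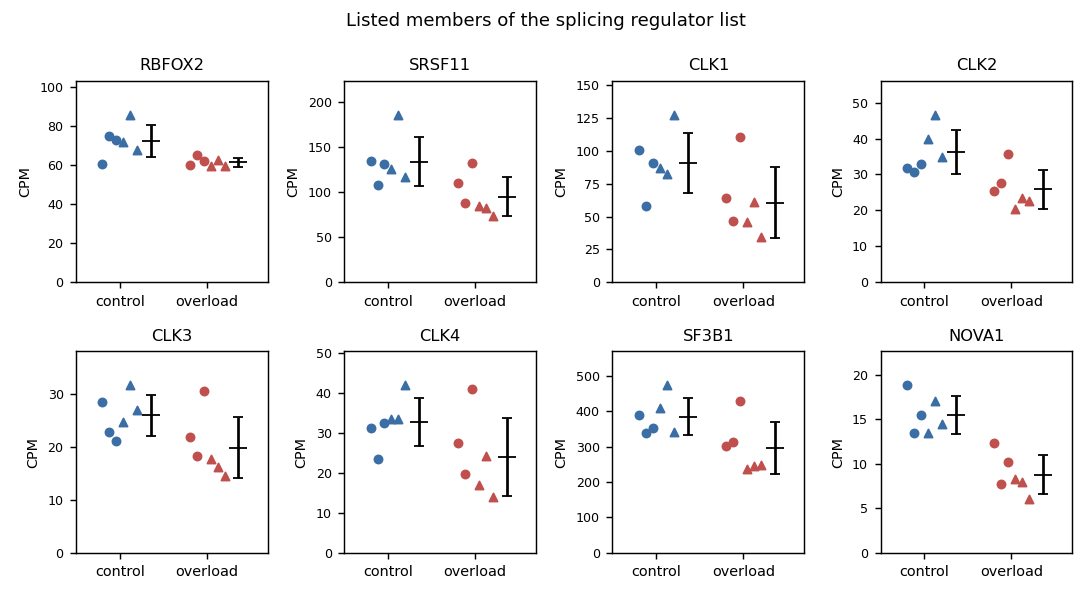
CPM of the 8 listed splicing regulators in 6 control (blue) and 6 pressure overload (red) libraries; circles are replicates 1 to 3, triangles replicates 4 to 6, and bars the mean ± SD. The means were lower in pressure overload for all 8 in the deposited scaling, with RBFOX2 at a log2 difference of 0.10 after median-of-ratios rescaling, and the median log2 difference was -0.13 in replicates 1 to 3 and -0.81 in replicates 4 to 6.

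In the list of the microRNA pathway and RNA decay, 3 of 54 members were listed, all lower (exact hypergeometric p = 0.276). PAN3, a subunit of a deadenylase complex, was at 42.5 ± 3.94 CPM in controls and 29.7 ± 8.45 CPM in pressure overload, the Argonaute protein AGO4 at 40.3 ± 8.30 and 31.7 ± 2.65 CPM, and its partner in silencing TNRC6A at 52.1 ± 7.28 and 40.2 ± 10.5 CPM (SD, n = 6 each). After median-of-ratios rescaling the log2 difference was -0.22 for PAN3 in place of -0.54, -0.00216 for AGO4 in place of -0.32 and -0.08 for TNRC6A in place of -0.40. The factors came from mostly lower genes, so this upward shift is built in. AGO4 overlaps CLSPN in the annotation, so its value is uncertain.

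In the hypertrophic and wall-stress list, 2 of 31 members were listed, both lower (exact hypergeometric p = 0.283): TNNI1, which fell as given above, and MYL4, the atrial and embryonic myosin light chain, at 24.9 ± 10.4 CPM in controls and 9.35 ± 4.78 CPM in pressure overload (SD, n = 6 each; exact permutation p = 0.0108). None of the 18 preset genes of wall stress and fibrosis, among them NPPA, NPPB, MYH7, COL1A1 and POSTN, was listed, and their values were not analysed here. Absence from a list chosen at an unadjusted p under 0.05 does not show that a gene did not differ. No gene was listed of 34 sarcomere and Z-disc genes, 60 genes of calcium handling and ion channels, 91 nuclear-encoded genes of oxidative phosphorylation or 36 of glycolysis. These counts describe the lists as written and not the gene classes. TNNI1 and MYL4 are sarcomere proteins counted in another list. The myosin MYH3 and the channel genes TRPM7, TRPC1 and SCN3B were among the listed genes outside these lists. Of 48 genes of fatty acid oxidation, 2 were listed, both lower (exact hypergeometric p = 0.487). CPT1A, which moves fatty acids into mitochondria, was at 33.0 ± 11.4 and 23.7 ± 5.71 CPM (exact permutation p = 0.121). The coactivator PPARGC1B was at 16.4 ± 4.32 and 11.97 ± 2.79 CPM (exact permutation p = 0.0628). The log2 differences of CPT1A and PPARGC1B, -0.42 and -0.41, were both -0.11 after median-of-ratios rescaling, which builds in an upward shift. Of 13 mitochondrially encoded genes, ND6 was listed (exact hypergeometric p = 0.361), at 15125 ± 2611 CPM in controls and 9215 ± 2976 CPM in pressure overload (exact permutation p = 0.00866, n = 6 each). ND6 overlaps ND5 in the annotation, and the strand setting of the counting is not given in the sources used here, so its value is uncertain.

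Immediate early and acute stress genes, a list fixed as a sign of sample handling, had 6 of 36 members listed, 4 higher and 2 lower, where at most 1.22 were expected (exact hypergeometric p = 0.00120, adjusted p = 0.0210 over 35 lists). Their share of higher genes did not pass the test against the other listed genes (Fisher's exact test, two-sided p = 0.0502, adjusted p = 0.10). NR4A3, an orphan nuclear receptor, was at 24.6 ± 14.96 CPM in controls and 78.7 ± 79.9 CPM in pressure overload, and its ratio of means of 3.20 was 1.91 without pressure overload replicate 3. The stress transcription factor ATF3 was at 21.8 ± 31.0 and 56.6 ± 38.1 CPM, and its ratio of 2.60 was 6.12 without control replicate 3. GADD45A was at 51.8 ± 17.7 and 75.9 ± 31.0 CPM, and the phosphatase DUSP1 at 65.3 ± 24.5 and 47.5 ± 9.29 CPM. Exact permutation p-values were 0.0281 for NR4A3, 0.0779 for ATF3 and for GADD45A, and 0.0714 for DUSP1. The log2 difference of DUSP1 was -0.41, and -0.09 after median-of-ratios rescaling. The same built-in upward shift took NR4A3 from 1.40 to 1.71 and ATF3 from 1.65 to 1.95. NR4A1 had a log2 difference of 0.43 and PER1, a clock gene, of -0.47. In limma, 0 of the 6 passed when adjusted over the list alone, and 0 when adjusted over all genes tested.

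Of 61 genes of cytokines and inflammation, 3 were listed (exact hypergeometric p = 0.341). The complement component C3 was at 52.3 ± 9.79 CPM in controls and 83.0 ± 20.4 CPM in pressure overload, the interleukin receptor IL6R at 26.6 ± 10.5 and 16.7 ± 3.01 CPM, and the chemokine CXCL10 at 102 ± 69.0 and 47.6 ± 21.3 CPM. Exact permutation p-values were 0.0108 for C3, 0.026 for IL6R and 0.113 for CXCL10. Of 40 interferon response genes, 2 were listed, CXCL10 and USP18 (exact hypergeometric p = 0.395). USP18 was at 37.3 ± 49.0 and 16.5 ± 5.23 CPM (exact permutation p = 0.476), and its ratio of 0.442 was 0.942 without control replicate 6. Within replicates 1 to 3 USP18 was higher in pressure overload, by 0.45 on the log2 scale, and within replicates 4 to 6 its log2 difference was -1.49. In the list of heat shock, unfolded protein response and autophagy, 2 of 45 were listed (exact hypergeometric p = 0.453). The count describes the list as written, since the heat shock protein genes HSPA4, HSPA14 and DNAJB6 were among the listed genes outside it. XBP1, a transcription factor of the unfolded protein response, was at 93.2 ± 9.14 and 115 ± 17.1 CPM. TRIB3, a pseudokinase induced by the same response, was at 0.496 ± 0.288 and 1.98 ± 1.92 CPM, and its ratio of 3.998 was 2.58 without pressure overload replicate 4. Within replicates 1 to 3 the log2 difference of TRIB3 was -0.07 and within replicates 4 to 6 it was 1.68. Of 47 ubiquitin ligases and proteasome genes, 2 were listed (exact hypergeometric p = 0.476): the muscle ubiquitin ligase FBXO32, at 269 ± 170 and 141.5 ± 34.8 CPM, and the proteasome subunit PSMD14, at 56.4 ± 3.52 and 69.6 ± 16.7 CPM. The exact permutation p was 0.00866 for FBXO32 and 0.0844 for PSMD14.

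Of 40 genes of angiogenesis and hypoxia, 4 were listed, 3 higher and 1 lower (exact hypergeometric p = 0.0455, adjusted p = 0.531), which did not pass. The VEGF receptor KDR was at 101 ± 27.5 CPM in controls and 150 ± 35.5 CPM in pressure overload (SD, n = 6 each; exact permutation p = 0.0281). HIF1A, the hypoxia-inducible factor, was at 82.0 ± 13.005 and 102 ± 12.6 CPM, the peptide hormone APLN at 20.1 ± 11.4 and 35.1 ± 15.9 CPM, and the Notch ligand DLL4 at 23.8 ± 6.37 and 18.1 ± 3.14 CPM. Exact permutation p-values were 0.00649 for HIF1A, 0.110 for APLN and 0.0996 for DLL4. The log2 difference of DLL4 was -0.35, and -0.04 after median-of-ratios rescaling. The same built-in upward shift took KDR from 0.57 to 0.90, HIF1A from 0.32 to 0.64 and APLN from 0.91 to 1.21.

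The genes of the cell type lists were not over-represented among the listed genes. These lists hold only some markers of each cell type, so the counts do not measure the makeup of the tissue. Of 183 genes in 11 cell type lists, 6 were listed, where at most 6.20 were expected (exact hypergeometric p = 0.590). The endothelial markers KDR and PLVAP were both higher, the latter at 98.5 ± 16.3 CPM in controls and 132 ± 26.4 CPM in pressure overload (2 of 19 members, exact hypergeometric p = 0.134). The macrophage marker CX3CR1 was at 6.96 ± 2.89 and 12.1 ± 3.17 CPM (1 of 21), and SCD, in the adipocyte list, at 5.54 ± 1.79 and 11.2 ± 5.69 CPM (1 of 14). Exact permutation p-values were 0.026 for PLVAP, 0.0195 for CX3CR1 and 0.0628 for SCD. The atrial list had MYL4 and COMP (2 of 16). No gene was listed among the markers of cardiomyocytes, fibroblasts, smooth muscle and pericytes, lymphocytes, neutrophils and mast cells, erythroid cells, or mesothelium, nerve and conduction tissue. None was listed of the cell cycle genes, the cytosolic ribosomal proteins, or the genes of renin-angiotensin, endothelin and cyclic GMP signalling.

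The libraries carry description numbers in 2 series, which divide each group into replicates 1 to 3 and 4 to 6. The genes listed lower had a median log2 difference of -0.25 within replicates 1 to 3 and -0.73 within replicates 4 to 6 (exact permutation p = 0.01 over 400 divisions of the libraries, two-sided). They were lower in pressure overload for 351 of 375 genes in the first set and 375 of 375 in the second. The genes listed higher had medians of 0.31 and 0.52 (exact permutation p = 0.105), with 138 and 141 of 141 higher. Of the 57 genes named by rule, 55 had the same sign in both sets, and the exceptions were USP18 and TRIB3, though listing on these libraries favours a shared sign. The median of all fitted differences was -0.41, and it was -0.10 after median-of-ratios and -0.21 after upper-quartile rescaling, a shift built in by factors computed on genes chosen for differing and mostly lower. The shift was nearly the same for each of the 44 fitted list members, with medians of 0.32 and 0.21. It brought small decreases close to 0 and enlarged increases, as for SERPINH1, from 0.28 to 0.60 and 0.49. RBFOX2 turned to 0.10 after median-of-ratios rescaling but stayed at -0.01 after upper-quartile rescaling.

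**Figure D4:**
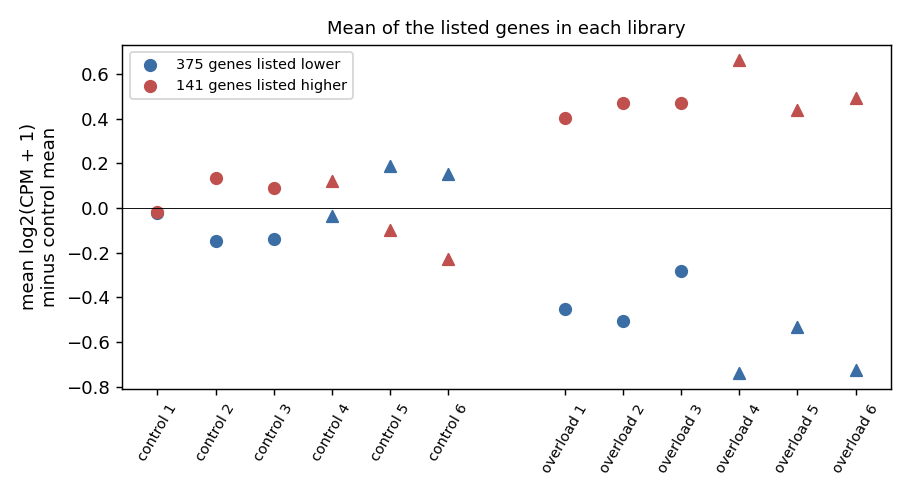
Mean log2(CPM + 1) of the 375 genes listed lower (blue) and the 141 genes listed higher (red) in each library, minus the control mean; circles are replicates 1 to 3 and triangles replicates 4 to 6. The genes were chosen because the groups differ, so the separation of the groups is built in; in pressure overload the lower genes lie between -0.28 and -0.74.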

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

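The tests of library scaling for the first 2 patterns below and of movement shared with other genes for the third were chosen after the results were seen.

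In each group of 6 libraries, a library was singled out when the ratio of its gap to the nearest other library over the group's range, on the log2 scale, exceeded Dixon's 95% critical value. This held for 9 of 120 groups, where chance gives about 6. TM4SF18 was lowest in control replicate 6, at 1.59 CPM against 6.57 to 9.40 in the others (ratio 0.772), and highest in pressure overload replicate 4, at 22.2 CPM against 13.4 to 14.9 (0.787). GRAMD1C was highest in control replicate 6, at 39.8 CPM against 16.0 to 18.9 (0.821), as was FBXO32, at 611 CPM against 168 to 248 (0.69995). In pressure overload replicate 4, COMP was at 7.44 CPM against 0 to 0.490 (0.813), GADD45A at 137 CPM against 52.1 to 73.5 (0.645), and the mean of the genes listed higher at 5.42 against 5.16 to 5.25 in log2(CPM + 1) (0.656). SERP1 was lowest in pressure overload replicate 6, at 13.97 CPM against 17.3 to 19.4 (0.642), and HIF1A lowest in control replicate 5, at 57.5 CPM against 80.8 to 93.8 (0.694).

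The genes listed lower differed more between pressure overload and control in replicates 4 to 6 than in replicates 1 to 3, by -0.488 in the median log2 difference. A chance division of the libraries is argued against by an exact permutation p of 0.01, and a single library by the ratio of the medians, 2.99, which stayed at 2.27 or more without any 1 library. Library scaling alone would move lower and higher genes the same way, but the set difference was -0.46 ± 0.12 (SE) for the library means of the lower genes and 0.219 ± 0.132 for the higher genes. Taken alone, the set difference of the higher genes did not pass (exact permutation p = 0.105 for the medians), so its sign is uncertain. Of 512 genes, 127 had an unadjusted interaction p under 0.05 in limma and 0 after adjustment over the table. What the description numbers stand for is not given in the sources used here, so a processing batch and a difference between animals both stay open, and no biological explanation was tested.

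Within groups, libraries in which the lower genes were low had the higher genes high. Pearson's r of the mean deviations was -0.82 (permutation p = 0.00028) and Spearman's rho -0.87 (permutation p = 0.00018) over 12 libraries, with adjusted p of 0.00056 and 0.00072 over 4 relations. The correlation was -0.91 in controls, -0.85 in pressure overload, -0.86 in replicates 1 to 3, -0.85 in replicates 4 to 6, and -0.85 without the 2 libraries farthest from the median, which argues against library scaling, under which it would lie above 0. Effective library size correlated with the lower genes at r = 0.33 (95% interval -0.38 to 0.79, permutation p = 0.288, adjusted 0.308; rho = 0.36, permutation p = 0.241; 0.35 without the 2 farthest), too wide to exclude depth. An axis of variation present in controls too, such as RNA quality or the makeup of the tissue sample, may contribute. Markers in the cell type lists were not over-represented among the listed genes (6 of 183) and immediate early genes were (6 of 36). Neither was tested against these deviations, and the cell type lists hold only some markers, so tissue makeup stays open.

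All 8 listed splicing regulators were lower in pressure overload in the deposited scaling, and RBFOX2 turned to 0.10 after median-of-ratios rescaling. That 8 of 8 stayed lower without any 1 library decides nothing, since all 375 genes listed lower did so and each was listed for its difference. The median of -0.48 was -0.16 ± 0.08 (SE) after median-of-ratios rescaling, which leaves scaling open too, because members and rescaling factors both come from genes chosen for differing, a limit the bound set beforehand overlooked. Movement shared with the other lower genes stays open: within groups their deviations correlated at r = 0.91 (permutation p = 0.00013, adjusted 0.00052; rho = 0.87, permutation p = 0.00127, adjusted 0.00254) and 0.88 without the 2 farthest libraries. The decrease of this list is therefore a hypothesis that may not be separate from the general lowering of the listed genes.

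Other splits of the libraries decide nothing about the counts of genes called by limma. The real groups gave 0 genes higher and 0 lower, so all 100 of 100 distinct splits, the real one included, gave at least as many by necessity, and the highest other split gave 0 higher and 1 lower.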

How the results depend on the processing

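The choice to adjust over 15235 genes, with the table alone as the alternative, and the hypergeometric test were made after the data were seen. Under every alternative that kept the adjustment over 15235 genes, limma called 0 genes higher and 0 lower, with a smallest adjusted p between 0.116 (median-of-ratios rescaling) and 1 (without pressure overload replicate 6). Adjusted over the table alone it gave 104 higher and 315 lower, which is circular by construction. Gene lists called numbered 0 by direction under each alternative, in a test of 2 lists that could not pass for the splicing list with all members lower, and 2 by the hypergeometric test, which could not be recomputed under them. At an adjusted p of 0.01 the authors' deposited table has 0 genes in place of 6. The 1264 values of 55 named genes under these alternatives, adjusted over 15235 genes, kept their direction and stayed short of the threshold; adjusted over the table alone, 45 of the 55 passed. The share of fitted genes that were lower was 73.0%, and 65.7% after median-of-ratios and 73.1% after upper-quartile rescaling, both computed on genes chosen for differing. Of the fitted genes, 456 had an unadjusted p under 0.05, against 195 after median-of-ratios and 241 after upper-quartile rescaling, 350 to 454 without 1 library, and 418 or more under the other alternatives. The planned count models were not run because not all values are whole reads, and the set tests with a preset or estimated correlation because the table is partial; the preset genes gave no value. Depth limits the low genes: COMP, at 0.117 CPM in controls, is near a few reads.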

Other observations

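The genes of this paragraph and the next, and KDM5D, were chosen after their values were seen, lie outside the fixed lists, and did not pass an adjusted test by limma or by the authors. MYH3, the embryonic myosin heavy chain, was at 5.76 ± 2.57 CPM in controls and 2.50 ± 0.691 CPM in pressure overload (SD, n = 6 each; exact permutation p = 0.00433). TBX4, a T-box transcription factor, was at 3.77 ± 1.64 and 1.117 ± 0.796 CPM, SCN3B, a sodium channel subunit, at 10.7 ± 6.05 and 3.97 ± 2.57 CPM, and NPNT, an integrin ligand of basement membranes, at 38.6 ± 24.3 and 12.8 ± 4.73 CPM. The secreted metalloproteinases ADAMTS3 and ADAMTS6 were at 10.9 ± 3.84 and 5.58 ± 1.72 CPM and at 60.3 ± 17.9 and 34.3 ± 16.0 CPM, while ADAMTS15 was at 11.12 ± 2.55 and 15.9 ± 3.33 CPM. CREB3L1, a transcription factor of the endoplasmic reticulum, was at 12.8 ± 3.79 and 18.5 ± 2.65 CPM, and ARCN1, a subunit of the COPI coat, at 93.9 ± 9.81 and 114 ± 4.50 CPM (exact permutation p = 0.00216).

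LUC7L3, a splicing-related protein, was at 186 ± 41.1 CPM in controls and 118 ± 38.4 CPM in pressure overload, with log2 differences of -0.27 in replicates 1 to 3 and -1.07 in replicates 4 to 6. SNRNP70, a protein of the U1 particle, was at 281 ± 82.0 and 178 ± 56.4 CPM (-0.13 and -1.22), and CCNL1, a cyclin linked to splicing, at 111 ± 27.1 and 73.1 ± 19.8 CPM (-0.20 and -0.99). SRRM2, a scaffold of nuclear speckles, was at 439 ± 72.4 and 328 ± 112 CPM, with log2 differences of 0.00 and -0.93. The difference between the sets was not tested for these 4 genes, and the 375 genes listed lower had medians of -0.25 and -0.73 in the same sets.

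The authors' deposited table lists 516 genes under an unadjusted p of 0.05, while 761.75 would be under it among 15235 genes if none differed and the p-values were uniform; whether the list was filtered further beyond the first 103 genes is not known. Within groups, ND6 and the mean of the lower genes correlated at r = 0.37 (95% interval -0.34 to 0.81, permutation p = 0.308; rho = 0.30, permutation p = 0.395; n = 12), and r was 0.18 without the 2 farthest libraries. It was 0.75 in replicates 1 to 3 and 0.05 in replicates 4 to 6, so the relation did not pass and is left open. KDM5D, a Y-linked gene in pigs, was above 0 in each of the 12 libraries, at 7.84 ± 1.81 CPM in controls and 4.75 ± 1.42 CPM in pressure overload, though reads shared with its X-linked copy were not separated here.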
